A study of Saccharina japonica with 2 samples.

How the data were processed

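Small RNA of the sporophyte blade of Saccharina japonica was sequenced after blue light treatment (1 library) and in the dark (1 library). Per the labels' protocols, total RNA with an integrity number of at least 8 was extracted with a CTAB method, RNA of 18 to 30 nt was purified on a gel, ligated to adaptors, amplified by RT-PCR and sequenced on a Solexa instrument. Per the file headers, the read tags were annotated against miRBase 18.0. The matching tool and the mismatches allowed are not given in the sources used here, and no reference genome was used here, so no coordinates are given.

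The counts as deposited are whole numbers of reads per miRNA name, in 1 list per library, with 1 sequence per name; the authors applied no scaling to them. How that sequence was chosen among the reads of a name is not given in the sources used here, so the count of a name may cover several sequences. A second table, deposited by the authors, holds normalised values in RPM, with 0.01 in place of 0. The counts divided by these values give 1 constant per library, which was taken as the library total (13498498 for blue light and 14208075 for dark). The same table of the authors holds the log2 ratio of blue light to dark, per the file headers, and a p-value whose test is not given in the sources used here. Samples were assigned to columns by the names in the headers. Names can share reads: in the blue light list 75 names had a sequence that lay within or contained that of another name, holding 0.656% of known reads, and in the dark list 63 names did, with 0.0963%.

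Each name's log2 ratio was computed from counts scaled by the library totals, with an exact 95% Clopper-Pearson interval conditional on the sum of its reads. A 0 was set to 3 reads, a one-sided limit that makes the ratio a bound; the two-sided 95% interval of such a name starts slightly nearer to 0. A two-sided exact binomial test on the reads was adjusted by Benjamini-Hochberg over the 963 names with at least 20 reads over both libraries. A name was counted as differing when its adjusted p was under 0.05 and its ratio at least 2-fold. With 1 library per group this test measures counting error alone. The test was checked on simulated data for the comparison of blue light with dark over 1961 names, 200 of them changed. The simulation held counting noise alone, so it gives no error rate for differences between libraries. The test called 92% of names changed by 1.5 on the log2 scale, 94% at 2, 98% at 3 and 100% at 4, and 0 of 764 unchanged names, and the intervals held the true ratio in 96.0% of names.

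Names were chosen by a rule fixed before the data were examined: the 10 highest mean levels, the 12 largest ratios in each direction, and the 3 most abundant members of each list. The text gives a part of these. Names among those with an identical sequence in both libraries, and names in groups of near-identical sequences, were chosen after their values were seen. Lists of land plant families (SPL/AP2 module, auxin-linked, copper-linked, sulfate and phosphate, HD-ZIP III, MYB/TCP, small RNA pathway, growth and transcription factors, conserved, light-linked), the let-7/miR-98 list, a list of abundant animal miRNAs and 4 lists by organism prefix were fixed before the data were examined. Lists of Ectocarpus and Chlamydomonas names were added afterwards, with the miRBase number ranges of both written from memory. For lists with at least 3 measured members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean level in 10 bins, as a description of these libraries.

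Alternatives were other scalings (the sum of known miRNA counts, TMM from edgeR 4.0.16, the median of ratios from DESeq2 1.42.0, and the sum without the 10 most abundant names), other minimums on reads and on the ratio, and an assumed biological coefficient of variation of 0.4. Added after the data were seen were the restriction to names with an identical sequence in both libraries and the sums over near-identical sequences, grouped by ungapped overlaps of at least 16 bases with at most 3 or 2 mismatches. Such groups are built by chaining, and the largest holds 194 sequences, so the summed values are described only for small groups. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9 and R 4.3.3 were used. Known animal and land plant miRNA sequences and stretches of ribosomal RNA were written from memory, after the deposited sequences had been seen, and were compared with the entries. Sequences identical to well known animal or land plant miRNAs are not printed.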

Results

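Small RNA was sequenced from the sporophyte blade of the kelp Saccharina japonica, a brown alga, after blue light treatment (1 library) and in the dark (1 library), to find microRNAs (miRNAs) that respond to blue light. The deposited values imply 13498498 reads for the blue light library and 14208075 for the dark library. Reads assigned to known miRNA names made up 46.6% of the blue light library (95% Clopper-Pearson interval 46.6 to 46.6%) and 40.7% of the dark library (40.7 to 40.7%). The blue light list held 1357 names with 6287856 reads and a median of 16 reads per name, and the dark list held 1370 names with 5779559 reads and a median of 18. Each condition had a single library, so no difference below has a replicate check, and the tests on reads compare these libraries, not the conditions. Intervals and floors cover counting error only. Levels are in RPM, the reads scaled to the library total. A name with 0 reads in a library was taken at a floor of 3 reads, which is 0.222 RPM in blue light and 0.211 RPM in the dark.

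A few entries held most of the known miRNA reads, and the leading entry differed between the libraries. In blue light it was miR-250-3p, represented by AACCAGTCAGACTGTTGTC, with 3352556 reads or 53.3% of the known reads, and this name had 0 reads in the dark. In the dark it was miR-1827, represented by TGAGGCAGTCAGATTGTT, with 2780978 reads or 48.1%, against 1001 reads in blue light under a different sequence. The 10 most abundant names of each library held 74.5% of the known reads in blue light and 73.5% in the dark. Among the 10 names with the highest mean level over both libraries, miR3461, a name of the Ectocarpus series of brown algal miRNAs, had 703096 reads in blue light and 73 in the dark (log2 ratio 13.31, 95% interval 12.98 to 13.66) under different sequences, and miR5219 had 110187 and 0. The name miR-4666a-5p had 9666 and 646557 reads (log2 ratio -5.99), also under different sequences, and miR-345 had 0 and 127483. The remaining 4 of these names differed less. miR-2898 had 50204 and 209085 reads (log2 ratio -1.98) and miR-219* had 65786 and 151223 (-1.13, -1.14 to -1.11), each with an identical sequence in both libraries. miR2088 (log2 ratio 0.71, under different sequences) and miR5386 (-0.14) stayed under 2-fold.

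The leading entries of both libraries were near-identical in sequence under different names. When sequences that overlapped by at least 16 bases with at most 3 mismatches were summed, miR-250-3p fell into 1 group with miR-1827, miR-4666a-5p and let-7h. This group took 24.9% of all reads in blue light and 24.1% in the dark, a log2 ratio of 0.05 (95% interval 0.05 to 0.05). The group led by miR3461, which held miR5219, kept a ratio of 11.71 on the log2 scale, with 813331 reads in blue light and 256 in the dark. However, the miR5219 sequence resembles both sequences listed for miR2088, with more mismatches than the rule allows. The group of miR2088 had 166278 reads in blue light and 107096 in the dark (log2 ratio 0.71) and was kept apart. The ratio of 11.71 therefore holds for this grouping alone. The names miR-84a (0 and 49092 reads) and miR-84b (47994 and 107 reads) also shared a group, with 48024 reads in blue light and 56458 in the dark (log2 ratio -0.16). Likewise, miR-19a* (43399 reads in blue light alone) shared a group with miR4230 and miR-26a* that had 56261 and 34381 reads (0.78), the group of miR-663b (32648 reads in the dark alone) had 10520 and 53446 (-2.27), and that of miR-4419a (7238 and 24 reads) had 7238 and 6099 (0.32). Among the names with the largest ratios, miR-345, miR-1593, miR-1645 and miR-2774a had no near-identical sequence under another name by this rule. The group of miR-135-1* had 70075 reads in blue light and 0 in the dark. However, the end of the miR-345 sequence and the start of the miR-135-1* sequence are alike over fewer than 16 bases, which the rule does not count. The opposite ratios of miR-345 and miR-135-1* may therefore not be independent. This grouping was chosen after the values were seen.

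**Figure D1:**
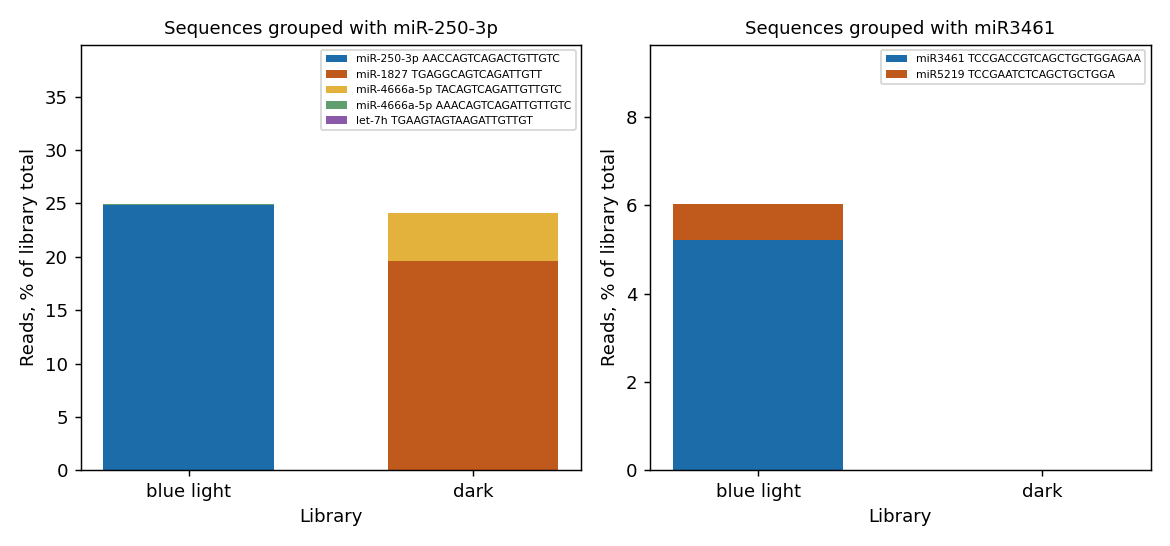
Reads as a percentage of the library total (vertical axis) in the blue light and dark libraries, for the sequences grouped with miR-250-3p (left) and with miR3461 (right). Colours mark name and sequence for members with at least 1000 reads. The left group took 24.9% of the blue light library and 24.1% of the dark library under different names, and the right group had 813331 reads in blue light and 256 in the dark.

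Of 963 names with at least 20 reads over both libraries, 672 differed at least 2-fold with a Benjamini-Hochberg adjusted exact binomial p under 0.05 on the reads, 328 higher and 344 lower in blue light. The largest positive ratios belonged mostly to names with 0 reads in the dark. After miR-250-3p (at least 20.17 on the log2 scale, against 0.05 for its group) and miR5219 (at least 15.24) came miR-135-1* (69610 reads, at least 14.58), miR-19a* (at least 13.89, against 0.78 for its group) and miR-1593 (35746 reads, at least 13.61). The largest negative ratios were those of miR-345 (-15.30 or lower), miR-84a (-13.92 or lower, against -0.16 for its group), miR-1645 (41320 reads in the dark, -13.68 or lower), miR-663b (-13.34 or lower, against -2.27 for its group) and miR-2774a (23183 reads, -12.84 or lower), all with 0 reads in blue light. The name miR-275* had 1 read in blue light and 7028 in the dark (log2 ratio -12.71, 95% interval -18.01 to -10.23), under different sequences with no near-identical overlap; the group of its dark sequence had 4640 and 7028 reads (-0.53).

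The sequence listed for a name was often not the same in both libraries. Of the 766 names present in both, 329 were listed with an identical sequence and 437 with a different one. Among names with at least 20 reads, 97 of 285 (34.0%) with an identical sequence differed, against 214 of 317 (67.5%) with a different sequence. The SD of the log2 ratio across names was 1.27 where the sequence was identical and 4.55 where it was not. How the listed sequence was chosen is not known, so this split may not be independent of the ratio. A name with 0 reads in 1 library and at least 20 in the other always passes these criteria. Names found in blue light alone held 62.5% of its known reads, most of them under miR-250-3p, and names found in the dark alone held 10.1%.

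**Figure D2:**
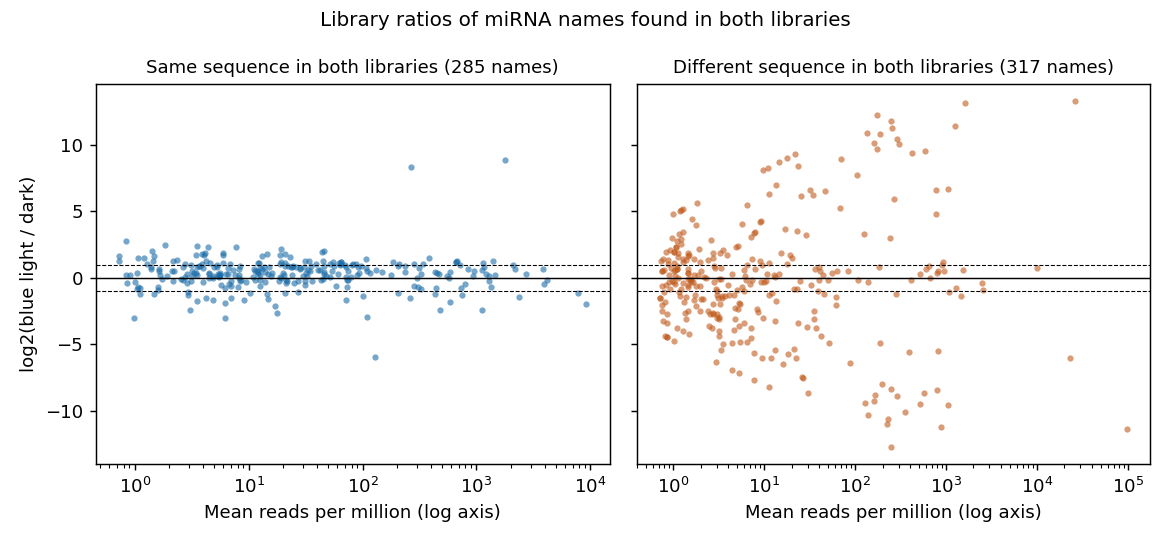
The log2 ratio of blue light to dark (vertical axis) against mean RPM on a log axis for names with at least 20 reads over both libraries and reads in each, 1 point per name. Dashed lines mark 2-fold. The 285 names listed with an identical sequence (left) spread less, with an SD of 1.27, than the 317 names listed with different sequences (right), with an SD of 4.55.

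Among names with an identical sequence in both libraries, 63 were higher and 34 lower in blue light by library totals. The median log2 ratio of the 285 such names with at least 20 reads was 0.37. Every other scaling tried lowered all ratios, with a shift of -0.29 under TMM, so the excess of higher names may depend on the scaling. The largest increases were miR-84b (log2 ratio 8.88) and miR-4419a (8.31), whose groups of near-identical sequences had -0.16 and 0.32. The next were miR831 (20 and 3 reads, 2.81, 95% interval 1.06 to 5.20), miR168 (42 and 8 reads, 2.47, 1.36 to 3.77) and miR156 (79 and 16 reads, 2.38, 1.59 to 3.25, against 1.52 for its near-identical group). Increases with more reads included let-7f-5p (995 and 255 reads, 2.04, 1.84 to 2.24, against 0.86 for its near-identical group), miR477 (954 and 258 reads, 1.96, 1.76 to 2.16) and miR-2127 (422 and 98 reads, 2.18, 1.86 to 2.51). The largest decrease was miR5485 (54 and 3563 reads, -5.97, -6.39 to -5.58), but with near-identical miR-2980, which matches a stretch of ribosomal RNA, its group had 40223 and 38775 reads (0.13). Other decreases included miR-4078-5p (344 and 2730 reads, -2.91), miR-1587 (2052 and 11338 reads, -2.39), miR-1584 (4858 and 26484 reads, -2.37), miR-2898 (-1.98) and miR-27a-5p (3525 and 12792 reads, -1.79). This restriction, and the names it brings in, were chosen after the values were seen.

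Of 21 names of conserved land plant families with at least 20 reads, 9 were higher, 5 were lower and 7 did not differ, and adjusted over the list alone the counts were again 9 and 5. Their median log2 ratio of 0.55 lay at percentile 77.8 of random lists matched on mean level. All names of this list made up 0.455% of known reads in blue light and 0.267% in the dark. Most of these reads were those of miR165, with 21090 of 28609 in blue light and 10354 of 15437 in the dark. The balance of higher and lower names depended on the scaling, with 3 higher and 6 lower under trimmed mean of M-values (TMM) scaling. Among the 14 names listed with an identical sequence, 7 were higher and 1 was lower by library totals, with a median of 0.97. Only 8 names had a listed sequence that matched a known land plant miRNA, as written from memory. They were miR156, miR162, miR166, miR167, miR168, miR172, miR390 and miR528. The family functions given below therefore go with the names and, for other members, not with a matching sequence. Both measured names of the SPL/AP2 module, which in land plants controls phase change, were higher: miR156 and miR157 (109 and 53 reads, log2 ratio 1.11). These names have near-identical sequences and form 1 group, with 188 and 69 reads (1.52, 95% interval 1.11 to 1.94). Of 2 HD-ZIP III names, miR165 was higher (21090 and 10354 reads, 1.10, 95% interval 1.07 to 1.13), while miR166 had a log2 ratio of 0.92. miR157 and miR165 fell under 2-fold with every other scaling tried, as did miR395. miR168, which targets AGO1 in land plants, was the measured name of the small RNA pathway list and was higher.

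**Figure D3:**
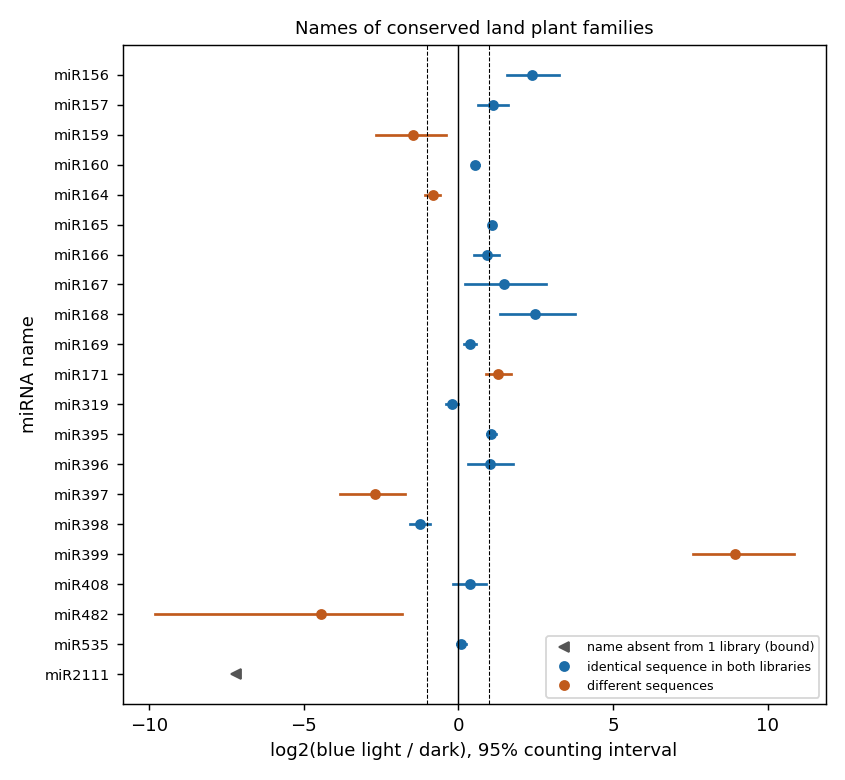
The log2 ratio of blue light to dark (horizontal axis, scaled by library totals) for the 21 names of conserved land plant families with at least 20 reads, with 95% counting intervals as lines. Colour marks whether the sequence was identical in both libraries, the triangle marks a bound for a name absent from 1 library, and dashed lines mark 2-fold. At this scaling 9 names were higher and 5 lower in blue light, against 3 and 6 under TMM scaling.

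The copper-linked families, which target copper proteins in land plants, contained 2 lower names of 3 measured and none higher. This function goes with the names. Of the names given in this paragraph, only miR167 had a listed sequence that matched a known land plant miRNA, as written from memory. miR398 had 286 reads in the dark and 116 in blue light (log2 ratio -1.23, 95% interval -1.55 to -0.91), and miR397 had 68 and 10 reads (-2.69) under different sequences. miR408 had a log2 ratio of 0.38 (-0.15 to 0.91). The list median was -1.23, at percentile 37.2. Of the sulfate and phosphate families, miR395 was higher (1178 and 593 reads in blue light and dark, 1.06), miR399 was higher under a different sequence (1897 and 4 reads, 8.96), and miR2111 had 0 and 459 reads (-7.18 or lower). The list median was 1.06, at percentile 79.1. Of the auxin-linked families, miR167 was higher (21 and 8 reads, 1.47, 0.23 to 2.85; under the TMM scaling it did not pass), and miR160 had a log2 ratio of 0.55. Of the MYB/TCP families, miR159 was lower under a different sequence (10 and 29 reads, -1.46) and miR319 had a log2 ratio of -0.20. Of the 4 names in the list of growth and transcription factor families, 2 were higher, among them miR171 (log2 ratio 1.29, 95% interval 0.89 to 1.70, under different sequences), and the median was 0.69, at percentile 66.1, or 0.37 with a minimum of 100 reads. With TMM scaling none of these 4 was higher and 1 was lower. The light-linked list, whose 14 names all belong to the conserved list, had 12 measured names, of which 5 were higher and 2 lower, with the same counts adjusted over the list alone and a median of 0.74 at percentile 81.8. Under TMM scaling 1 was higher and 2 were lower, and among the 10 names with an identical sequence 4 were higher and 1 was lower by library totals.

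Names used for animal miRNAs were also found. Of 14 measured let-7/miR-98 names, 5 were higher in blue light and none lower (5 and 0 adjusted over the list alone), with a median log2 ratio of 0.87 at percentile 85.8. Some of these names stand for the same known miRNA, as let-7b and let-7b-5p do, so the members are not independent. The name let-7-5p had 27863 reads in blue light and 280 in the dark, under different sequences. Of the 9 names listed with an identical sequence, 2 were higher, let-7f-5p and let-7e (71 and 37 reads, log2 ratio 1.01). With each other scaling tried, the whole list had 4 higher names and none lower. Among the other higher names, let-7h belongs to the group of miR-250-3p (log2 ratio 0.05). The names let-7-5p and let-7d had near-identical sequences in blue light that form 1 group of 35986 and 0 reads. Their dark sequences lie in another group, with 2366 reads in blue light and 1376 in the dark (0.86). The end of the blue light let-7-5p sequence is identical to the start of that of miR-4078-5p (344 and 2730 reads) over fewer than 16 bases. The grouping does not count this overlap, so the 0 dark reads hold for that grouping alone. Of 46 measured names on the list of abundant animal miRNAs, which holds 16 of the let-7/miR-98 names, 19 were higher and 9 lower (19 and 8 adjusted over the list alone). With an identical sequence 7 of 22 were higher and 1 was lower. The median over the list was 0.83, at percentile 94.6, or 0.49 with no minimum on reads. Its most abundant name was miR-191* (36487 and 24128 reads, log2 ratio 0.67), whose sequence also matches a stretch of 18S ribosomal RNA with at most 2 mismatches. This list made up 1.63% of known reads in blue light and 0.882% in the dark. By naming style, plant or alga names held 20.7% of known reads in blue light and 8.95% in the dark, animal names 78.9% and 90.4%, and virus names 0.378% and 0.635%. The plant or alga share in blue light rests largely on miR3461. That name held 703096 of the 1300518 reads of this style in blue light and 73 of 517300 in the dark, under different sequences. The style says which series a name comes from, not which organism the read came from.

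The lists of Ectocarpus and Chlamydomonas names by number were added after the names were seen, because the names carry no organism prefix and the 4 prefix lists matched 0 names. Of 5 measured Ectocarpus names, 4 were higher in blue light and none lower, among them miR3464 (20566 and 218 reads under different sequences, log2 ratio 6.63) and miR3450 (1693 and 0 reads, at least 9.21). All 12 names of this list, miR3461 among them, made up 11.5% of known reads in blue light and 0.00637% in the dark. The median log2 ratio of the Ectocarpus list was 6.63, but 0.13 with no minimum on reads. Of 14 measured Chlamydomonas names, 4 were higher and 4 lower, with a median of 0.19 that lay at -0.10 under TMM scaling and at 0.88 with a minimum of 100 reads. The name miR910 had 61 reads in blue light and 22566 in the dark (-8.46), under different sequences.

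More names were found in 1 library alone than depth would give. There were 591 names with reads in blue light alone and 604 in the dark alone, where splitting each name's reads by depth gave 161 and 175. With at least 10 reads the numbers were 231 and 271, against 0.0459 and 0.0797.

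The authors' deposited table compares 1016 names, of which 724 carry 2 stars and 15 carry 1 star, 358 of the marked names higher and 381 lower in blue light. Every name in the authors' deposited table reached at least 1.04 RPM in 1 of the libraries, and the highest level among the 945 names left out was 0.985 RPM. The value 0.01 stands in place of 0 in the authors' deposited table, and ratios there reach 24.57 on the log2 scale. With that value the log2 ratio computed from the counts matched the authors' deposited table within 0.01 for all 1016 names. All 672 names that differed here were marked in the authors' deposited table, which marked 67 more. Marks in the authors' deposited table covered 35.0% of names with an identical sequence, against 70.4% with different sequences.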

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

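Tests restricted to names with an identical sequence, and sums over near-identical sequences, were chosen after the data were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out. Other scalings moved every log2 ratio by -0.14 (sum without the 10 most abundant names), -0.20 (sum of known miRNA counts), -0.22 (median of ratios) or -0.29 (TMM), and the count of differing names stayed between 650 and 658, against 672. The balance of directions shifted, with 287 names higher and 363 lower under TMM, against 328 and 344 by library totals. The count was 910 with no minimum on reads, 823 with no minimum ratio, 537 at 4-fold and 559 with an assumed coefficient of variation of 0.4. With a minimum of 100 reads 413 names differed, 202 higher and 211 lower, because fewer names were tested. With an identical sequence in both libraries 97 differed by library totals, 63 higher and 34 lower, out of fewer names. Sums over near-identical sequences gave 521 differing groups with 3 mismatches and 611 with 2. With 3 mismatches 69.9% of 745 groups differed, against 69.8% of names. These percentages do not show that grouping left the calls unchanged. A name listed with different sequences can split into groups with reads in 1 library alone, which always pass at 20 reads. Of all 1746 groups, 429 had reads in both libraries. Counting every name on its own changed nothing, since no entries were collapsed. The Chlamydomonas median changed sign, to -0.0011 with the sum of known counts and -0.10 with TMM, and was 0.88 with a minimum of 100 reads; the sign also changed for miR1158, at -0.037 (sum of known counts), -0.14 (TMM) and -0.058 (median of ratios), by the shift of the scaling. miR157, miR165 and miR395 fell under 2-fold with all 4 other scalings, miR167 and miR171 did not pass with TMM, and miR164 passed as lower with 3 of them. Without the most abundant entry, shares of known reads in blue light and dark were 0.975% and 0.515% for conserved land plant names, 3.49% and 1.70% for abundant animal names, and 44.3% and 17.3% for the plant or alga style. Over the library total they were 0.212% and 0.109%, 0.759% and 0.359%, and 9.63% and 3.64%; both follow from the denominator. Names found in blue light alone numbered 306 at 5 reads and 231 at 10, and in the dark alone 353 and 271, fewer by construction. Agreement with the authors' deposited table held for 597 names with reads in both libraries, for 1016 with 0.01 in place of 0, and for 0 with the sum of known counts, which is another denominator. Depth limits names near 20 reads, whose intervals span several-fold.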

Other observations

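All tests in this part were chosen after the results they bear on had been seen, and the known animal, land plant and ribosomal sequences used were written from memory after the deposited sequences had been seen.

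The sequences listed were short. Those of 18 to 20 nt made up 57.8% of names in blue light and 57.5% in the dark, and held 78.3% and 90.8% of known reads. By reads, the first base was mostly A in blue light (56.7%) and T in the dark (78.4%), while by names T was the most frequent first base in both (46.2% and 44.2%). These values by reads rest largely on miR-250-3p, which held 53.3% of the blue light known reads, and on miR-1827, which held 48.1% of those in the dark, near-identical sequences that start at different bases. Virus-style names with at least 20 reads included 3 that were higher and 13 that were lower in blue light.

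Names with large ratios were common. Near-identical sequences given different names in each library are a candidate explanation for part of them: 15.98% of the 1195 names absent from 1 library had a near-identical sequence in the other, against at most 5.10% in 20 shuffles. The shuffles cannot decide this, because the lists hold several names of the same family, whose sequences are alike whatever the cause of the ratios. Among names with at least 20 reads the share was 23.5%, so most of them had no listed counterpart by this rule. Whether different names for near-identical sequences are the whole cause cannot be decided from this. The rule misses gapped or shorter overlaps, as between miR-345 and miR-135-1*, and reads whose sequence is not listed. By reads the share was 88.3% for names found in blue light alone and 35.3% for those in the dark alone. The blue light value rests on miR-250-3p, which held 3352556 of the 3469112 reads with a near-identical sequence in the dark. Whether each name counts the same RNA in both libraries stays open, because a count can cover more than the listed sequence. Of the 311 differing names present in both, 53.4% had listed sequences with no near-identical overlap. The 311 include the names of identical sequence. Among the 214 differing names listed with different sequences the share was 77.6%, against 63.1% of all 317 such names with at least 20 reads. A response of the blades to blue light stays open, because the 97 names with an identical sequence that differed come from 1 library per condition, and light and library cannot be told apart.

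Of 8 names that matched known land plant miRNAs, the 4 listed with an identical sequence in both libraries and at least 20 reads (miR156, miR166, miR167 and miR168) had a median log2 ratio of 1.92 from 291 reads in blue light and 115 in the dark, and 3 of them passed the test on reads. A scaling difference as the cause is argued against, since this exceeded the median of all names with an identical sequence by 1.55. Reads carried over from animal and land plant material may contribute, as a hypothesis: of 50 names that matched known animal miRNAs, the 13 listed with an identical sequence in both libraries and at least 20 reads had a median of 0.81, with 12 above 0. That test is weak, because names left out by this restriction went both ways (let-7-5p at 6.71, miR-10a at -10.97) and 69.5% of all names with an identical sequence were above 0. The animal median exceeded that of all names with an identical sequence by only 0.43. Some of the 13 names also stand for the same known miRNA, as let-7b and let-7b-5p or miR-199 and miR-199a-3p do. A response to blue light at the median of 1.92 cannot be told apart from a library difference with 1 library per condition.

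Some entries may lie within longer RNAs. In the blue light library 46 names overlapped another name by at least 12 bases at an offset of at least 3 bases, against at most 4 in 20 shuffles, and in the dark library 54 did, against at most 6, so fragments of longer RNAs cut at many places may be among the entries. Fragments of ribosomal RNA matched 7 names in blue light and 6 in the dark, with 1.72% and 1.43% of known reads. This cannot be told from the match, because the ribosomal stretches were recalled after the entries had been seen. No biological explanation was tested for this pattern.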
